A study of Mus musculus with 4 samples.

How the data were processed

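ATAC-seq libraries were made from mpkCCD clone 11 cells after 30 minutes of 0.1 nM dDAVP or vehicle, with 50000 cells per library and paired-end reads of 50 bases, per the labels' protocols. The submitters' processing notes name cutadapt, Bowtie2, SAMtools, Picard, bedtools and MACS2 and the build mm10, with no versions, roles or settings, so the order of steps, the peak threshold, the handling of duplicate and mitochondrial reads and any shift of reads for the transposase cut are not given in the sources used here. The authors deposited 1 peak list per library, so peaks were called per sample as far as the files show, with 3 columns (chromosome, start and end) and no header, score, summit or depth. The only measured values in them are positions and presence, and no intensity of a peak could be compared. Within each list no peaks overlapped and none was repeated. A more deeply sequenced library yields more called peaks, and the lists differed in length by 1.91 times, so presence and absence are not comparable between libraries without a comparison of splits that do not follow the treatment. The depth per library is unknown, and no interval that needs it is given.

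Treatment and replicate number were taken from the sample titles. Peaks of all libraries that overlapped by 1 bp or more were merged into regions, with touching peaks kept apart, and a region was present in a library with any peak there. Coordinates are given 1-based. Gene positions came from a RefSeq gene table on GRCm38.p6, the assembly that mm10 names, with 21887 protein-coding genes, and all 324 entries of the 12 gene lists (323 distinct genes) matched it. That table gives no strand, exons or sequence. The window planned around transcription start sites was therefore replaced by windows of 1 kb around both outermost ends of each gene, 1 of which is the annotated start, and a gene whose main promoter is internal is missed by it. Regions were placed at gene ends, inside genes or outside genes without a split into exons and introns. Tests of 24 sequence motifs were planned and not run, because no sequence was used here. Alternatives that needed a peak score were replaced, after seeing the data, by the widest 205771 peaks of each library (the length of the shortest list) and by peaks at least as wide as the median of their library, and peaks were ranked by width where the plan named the score.

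Numbers of peaks and covered lengths were compared with exact two-sided permutation tests (2 against 2). Treatment-specific regions were counted beside the same counts for the other 2 ways to split the libraries into pairs. The odds ratio of same-direction differences and its interval from a bootstrap of 5 Mb blocks were chosen after seeing the data. Lists were tested with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment at 0.05, and with exact conditional tests within chromosomes added after seeing the data. Regions outside gene-end windows and within 50 kb of a gene were counted against 10000 random gene lists, for which the smallest possible two-sided p is 0.0002. Intervals on shares are exact binomial intervals and cover counting error only. The widths of all-library regions were compared on the log2 scale after quantile normalization with limma.

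The lists (principal cell, cAMP and PKA signalling, cAMP-responsive early genes, bZIP transcription factors, corticosteroid-responsive genes, epithelial junctions and keratins, intercalated cell, proximal tubule, thick ascending limb and distal convoluted tubule, podocyte with endothelium, stroma and leukocyte, housekeeping, and genes of other organs), the main tests and the rule for named genes were fixed before the data were examined. By that rule the text names Aqp2 and the regions within 100 kb of it, every list gene with a peak in both libraries of 1 treatment and neither of the other, up to 4 members of each list with a gene-end peak in all 4 libraries (the widest by rank within each library) and up to 4 without one in any, and 10 regions specific to each treatment. Some items that the rule takes are not reported here. Further members named for their values (Scnn1a, Scnn1g, Hsd11b2, Gata3, Elf3, Avpr2, Aqp3, Scnn1b, Lhx1, Egr2 and the genes named in the account of regions away from gene ends and in the closing section) were chosen after their values were seen, and of the regions around Aqp2 those present in all libraries and wide, or treatment-specific, are given in full.

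The steps were tested on simulated data. All of 47304 simulated sites were given the right pattern of libraries. Those sites lay too far apart to merge with each other, so this checks the code and not the merging of close peaks. For the test of open gene ends, simulated with independent genes, 3.5% of 200 unchanged lists were called at an unadjusted 0.05. In the same simulation 97% of lists of 30 genes with 9-fold odds were called, and the odds ratio recovered for 200 genes with 9-fold odds was 13.6. The tests of gained and lost gene-end peaks were not simulated. The width comparison was simulated with the mean widths of the 88231 real regions and a single pooled residual SD (0.676 on the log2 scale). In it 0% of changes of 2-fold and 72.2% of changes of 8-fold were recovered. A spread that differs between regions was not simulated, so recovery in the real data may differ. This simulation replaced an earlier one on idealised widths. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used. Alternatives covered the gene-end window (0.5 and 2.5 kb), a reciprocal overlap of 50%, a merging gap of 100 bp, assembled autosomes and X alone, the distance to genes (100 kb), the background of random genes, and leaving out each library in turn. With the reciprocal overlap, peaks of the replicate 1 library of a treatment or crossed pair were counted in place of merged regions.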

Results

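Chromatin accessibility was measured with ATAC-seq, in which a transposase cuts exposed DNA and the cut sites pile up into peaks. The cells were mpkCCD (clone 11), a mouse line with features of the cortical collecting duct, where vasopressin controls water reabsorption through the water channel aquaporin-2 (Aqp2). Cells grown to confluence on permeable supports were moved to medium without serum or hormones and given 0.1 nM dDAVP, a vasopressin analog selective for the V2 receptor, or its vehicle for 30 minutes. There were 4 libraries, 2 per treatment, each made from 50000 cells and each deposited as its own peak list. The labels do not say whether the libraries of a treatment came from separate cultures, so the spread between them may be technical. All coordinates are on mm10.

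The lists held 393956 peaks for vehicle replicate 1, 291454 for dDAVP replicate 1, 206972 for vehicle replicate 2 and 205771 for dDAVP replicate 2. Peaks covered 133 Mb, 97.8 Mb, 74.2 Mb and 73.6 Mb of the genome in the same order, and their median widths were 239, 233, 246 and 246 bp. A peak lay within 1 kb of an annotated gene end at 78.2%, 74.2%, 70.0% and 69.4% of the 21887 protein-coding genes, again in that order. The lists give positions alone, so the number of reads behind each peak is unknown and a missing peak is a site that was not called, not a site shown to be closed. In the gene groups below, a gene is called open where a peak lies within 1 kb of either of its ends. That peak may lie at the far end of the gene or at a neighbouring gene, so an open gene need not have an accessible promoter. The widths given for a gene are those of its widest peak within 1 kb of a gene end, as mean ± SD over the 4 libraries.

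Peaks were spread unevenly over the chromosomes in every library. Chromosome 19 had the highest median density over the libraries, 249 peaks per Mb, followed by chromosome 12 with 220, and X had the lowest of the chromosomes 1 to 19 and X with 15.5, a 16.1-fold range. Chromosomes 18, 7 and 4 had 22.7, 34.3 and 35.5 peaks per Mb. On chromosome 13 the median number of merged regions per Mb was 174 before 64 Mb and 39 after it. A gene-end peak in all 4 libraries was found at 29.8% of the genes on X, 50.7% on chromosome 18 and 89.5% on chromosome 12, and the gene lists below were therefore also tested within chromosomes.

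**Figure D1:**
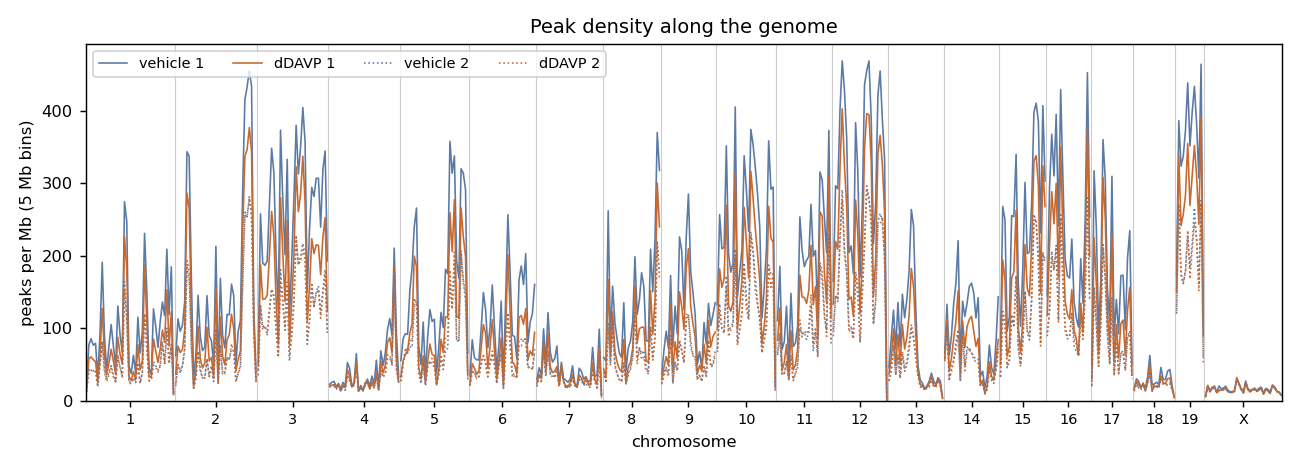
Peaks per Mb in 5 Mb bins (vertical axis) along chromosomes 1 to 19 and X (horizontal axis), with 1 line per library, blue for vehicle and orange for dDAVP, solid for replicate 1 and dotted for replicate 2. The 4 lines have similar profiles, but the gap between them varies by chromosome. Vehicle replicate 1 had 2.19 times as many peaks as dDAVP replicate 2 on chromosome 9 and 1.06 times as many on X. All 4 lines are low along most of chromosomes 4, 7, 18 and X, where the median densities over the whole chromosome were 35.5, 34.3, 22.7 and 15.5 peaks per Mb, with a sharp rise near the end of chromosome 4.

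The first comparison asked which genes were accessible in these cells under either treatment. The listed genes of the epithelial junctions and keratins were open almost throughout, with a gene-end peak in all 4 libraries at 27 of 28 (96.4%), against 64.9% of the other protein-coding genes. The list is a choice of members. Of all keratin (Krt) genes 35 of 53 were open, of all claudin (Cldn) genes 14 of 35 and of all cadherin (Cdh) genes 8 of 23. The widest peaks of the list belonged to Esrp2, an epithelial splicing regulator (2611 ± 229 bp), the keratin Krt8 (2334 ± 297 bp), the desmosomal protein Dsp (2123 ± 154 bp) and the tricellular junction receptor Lsr (2017 ± 18.2 bp). Genes for bZIP transcription factors, the class that holds the CREB, C/EBP and AP-1 proteins, were open in all 4 libraries at 34 of 34, led by Ddit3 (3131 ± 163 bp), Nfe2l2 (1969 ± 44.9 bp), Maff (1713 ± 15.4 bp) and Bach2 (1701 ± 49.5 bp). The cAMP-responsive early genes were open at 29 of 30, among them Jun (2517 ± 362 bp), Egr1 (2375 ± 315 bp), Cebpb (2014 ± 114 bp) and Jund (1952 ± 49.2 bp). The remaining early gene, Egr2, had a gene-end peak in vehicle replicate 1 alone. At the other end, marker genes of podocytes, endothelium, stroma and leukocytes had such a peak at 9 of 30 (30.0%).

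These 4 lists and the housekeeping list were the ones that differed from the other protein-coding genes, by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 12 lists. Adjusted p was 6.85e-06 for the bZIP factors, 0.000373 for the early genes, 0.000445 for the epithelial genes, 0.000445 for the housekeeping genes and 0.000445, in the lower direction, for the podocyte, endothelial, stromal and leukocyte markers. Within chromosomes, all 5 lists stayed past the threshold, with adjusted p of 2.66e-05, 0.000482, 0.00201, 0.000338 and 0.000338 in the same order. The lower share of the non-epithelial markers lost its call with windows of 2.5 kb (adjusted p = 0.160), with the whole gene as the window (0.163) and with a peak in any 1 library sufficing (0.837), and the last setting also ended the housekeeping call (0.140). Genes are not replicates, so these tests describe the 4 libraries and not a population of cultures.

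Among markers of the principal cell, the vasopressin-responsive cell of the collecting duct, 18 of 26 were open in all 4 libraries (69.2%, adjusted p = 0.837). They included Aqp2 (773 ± 157 bp), the alpha and gamma subunits of the epithelial sodium channel, Scnn1a (1200 ± 27.6 bp) and Scnn1g (665 ± 92.5 bp), the glucocorticoid-inactivating enzyme gene Hsd11b2 (1138 ± 144 bp) and the transcription factors Gata3 (1341 ± 391 bp) and Elf3 (1166 ± 45.1 bp). By width the leading members were St6gal1 (1919 ± 231 bp), the prostaglandin receptor gene Ptger4 (1444 ± 181 bp), Ehf (1430 ± 167 bp) and Hoxd8 (1372 ± 20.1 bp). No gene-end peak was called in any library at Aqp4, Kcnj1, Nedd4l or Slc14a2. Of these, Aqp4, Nedd4l and Slc14a2 are on chromosome 18, where few peaks were called, and Kcnj1, Nedd4l and Slc14a2 had a peak elsewhere in or within 1 kb of the gene in all 4 libraries. The vasopressin receptor gene Avpr2, on X, had a gene-end peak in dDAVP replicate 1 and vehicle replicate 2 only. Aqp3, Scnn1b and Lhx1 had one in both replicate 1 libraries and neither replicate 2 library.

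Genes of cAMP and protein kinase A signalling, the pathway downstream of the V2 receptor, were open at 22 of 30 (73.3%, adjusted p = 0.592). Prkaca, a catalytic subunit of protein kinase A, had the widest peak (2179 ± 25.8 bp), followed by the salt-inducible kinase gene Sik1 (1826 ± 190 bp), the adenylyl cyclase gene Adcy6 (1817 ± 110 bp) and the cAMP-activated exchange factor gene Rapgef3 (1707 ± 144 bp). The anchoring protein gene Akap7 and the phosphodiesterase gene Pde4d had no gene-end peak in any library, although both had one elsewhere in or beside the gene in all 4. With the whole gene as the window, 29 of 30 were open and the list passed (adjusted p = 0.0181). That setting was not matched on gene length, and a longer gene has a longer window.

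Corticosteroid-responsive genes were open at 13 of 19 (68.4%, adjusted p = 0.837), led by Ddit4 (2232 ± 173 bp), Klf9 (2135 ± 198 bp), Cnksr3 (2017 ± 101 bp) and Fkbp5 (1509 ± 173 bp). Nr3c1, which encodes the glucocorticoid receptor, and Sult1a1 had no gene-end peak but had a peak elsewhere in or within 1 kb of the gene in all 4 libraries. The housekeeping genes were open at 26 of 27, with Gapdh (2407 ± 137 bp), Hsp90ab1 (1945 ± 29.3 bp) and Actb (1760 ± 84.5 bp) among the widest. The exception was Reep5, on chromosome 18.

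Markers of other kidney cells did not differ from other genes by the same test, and the lists were not tested against each other. Intercalated-cell genes were open at 11 of 20 (55.0%, adjusted p = 0.534), including the anion exchanger gene Slc26a4 (1048 ± 317 bp), the proton pump subunit gene Atp6v1b1 (873 ± 308 bp), Dmrt2 (869 ± 37.1 bp) and Hepacam2 (782 ± 220 bp), while Atp6v1g3, Hmx2, Oxgr1 and Spink8 had no gene-end peak. Proximal tubule genes were open at 14 of 24 (58.3%, adjusted p = 0.629), including Miox (1435 ± 430 bp), the endocytic receptor gene Lrp2 (1204 ± 281 bp), Ass1 (1082 ± 359 bp) and Pdzk1 (852 ± 310 bp). Acsm2, Cyp2e1, Kap and Slc7a13 had no peak in any library, either at a gene end or inside the gene. Thick ascending limb and distal convoluted tubule genes were open at 7 of 16 (43.8%, adjusted p = 0.192), among them Wnk4 (1873 ± 115 bp), Ppp1r1b (1225 ± 310 bp), Cldn14 (902 ± 96.1 bp) and Pvalb (476 ± 132 bp), and Calb1, Trpv5 and Umod had no gene-end peak. Over all lists, 36 genes had no gene-end peak in any library. Of these, 24 lie on chromosomes X, 18, 7, 4 and 13, which have the lowest peak density and hold 26.0% of the list genes. Those chromosomes were picked for their few peaks, so part of this excess is built in. Genes of families that every cell uses, described below, were open at 79 of 84 there and at 257 of 268 elsewhere, so most gene ends there could be called. A site without a called peak is not shown to be closed, so a missing peak at a marker is not by itself information on cell type.

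The non-epithelial markers that were open in all 4 libraries included the endothelial genes Flt1 (1453 ± 150 bp) and Plvap (771 ± 238 bp), the collagen gene Col1a1 (1215 ± 126 bp) and Wt1 (1147 ± 575 bp). The complement genes C1qa and C1qb and the collagen gene Col3a1 had no gene-end peak in any library. Genes of other organs, fixed as a comparison set, were open at 21 of 40 (52.5%, adjusted p = 0.192), among them Mbp (1589 ± 212 bp), Lor (1401 ± 47.5 bp), Actn3 (1293 ± 87.3 bp) and Apoa2 (1168 ± 168 bp), while Alb, Ckmt2, Ddx4 and Hbb-bt had no gene-end peak. With windows of 0.5 kb this list fell to 13 of 40. The thick ascending limb and distal convoluted tubule list fell to 4 of 16. Both lower shares did pass there (Fisher's exact test, adjusted p = 0.00235 and 0.0145).

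**Figure D2:**
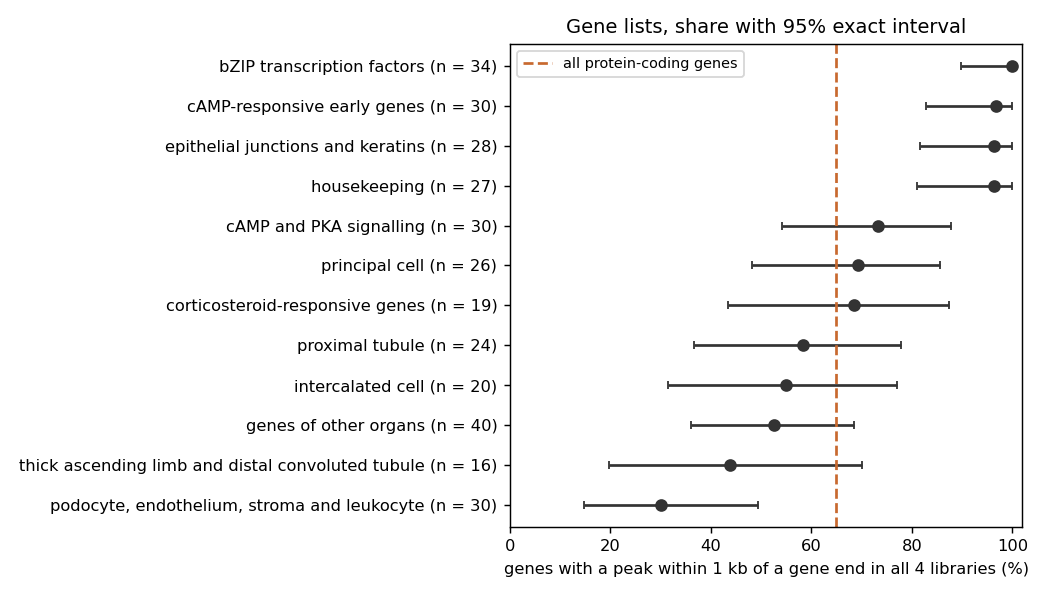
Share of each gene list with a peak within 1 kb of a gene end in all 4 libraries (horizontal axis, percent; points, with exact 95% binomial intervals as bars, which cover counting error only), with the number of genes in each list beside its name. The dashed line is the share over all protein-coding genes, 65.0%, and the bZIP factors, early genes, epithelial genes and housekeeping genes lie to its right with intervals that do not reach it.

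The second comparison concerned accessible regions away from gene ends. Around genes of cAMP and protein kinase A signalling there were on average 8.40 regions per gene that were present in all 4 libraries, outside every gene-end window and within 50 kb of the gene, against a median of 4.97 for 10000 random lists of the same size. The protein kinase A regulatory subunit gene Prkar1b had 24 such regions, Adcy9 had 21, Prkar2b had 20 and Adcy3 had 19. Epithelial genes had 8.18 on average against 4.96, with 22 around the epithelial transcription factor gene Grhl2, 19 around Krt8 and 17 around the cadherin gene Cdh1. The adjusted two-sided permutation p was 0.0324 for both lists.

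Corticosteroid-responsive genes averaged 8.42 regions (adjusted p = 0.0608), with 23 around Cnksr3 and 19 around Fkbp5. Principal-cell genes averaged 7.38 (0.0996), with 25 around Pax2, 21 around St6gal1 and 13 around Aqp2, and early genes averaged 6.77 (0.162), with 16 around Nr4a1 and 13 around Fos. The bZIP factors averaged 6.50 (0.183), thick ascending limb and distal convoluted tubule genes 7.81 (0.131), proximal tubule genes 6.58 (0.237) and intercalated-cell genes 5.70 (0.631). Genes of other organs averaged 5.33 (0.756), housekeeping genes 5.19 (0.847) and non-epithelial markers 4.37 (0.631). With random genes matched on chromosome and length, the corticosteroid-responsive (adjusted p = 0.00720), early (0.0216), principal-cell (0.0288) and epithelial lists (0.0288) were above chance and the cAMP list was not (0.310). With random genes matched on the number of libraries with a gene-end peak no list passed, and the cAMP and epithelial lists were at 0.0936 and 0.134.

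The third comparison, and the one the study was built on, set 30 minutes of dDAVP against vehicle. Of 560228 merged regions, 9045 (1.61%) had a peak in both dDAVP libraries and neither vehicle library, and 18759 (3.35%) had a peak in both vehicle libraries and neither dDAVP library. These counts were close to those of pairs that cross the treatments. Vehicle replicate 1 and dDAVP replicate 2 alone shared 17736 regions, and dDAVP replicate 1 and vehicle replicate 2 alone shared 8774. With each library cut to its widest 205771 peaks, a setting chosen after seeing the data, there were 11325 dDAVP-only and 12381 vehicle-only regions. Such a cut would also remove a broad loss of peaks, so it does not decide the source of the imbalance. Both replicate 1 libraries alone shared 49261 regions and both replicate 2 libraries alone shared 6642. Each count rested on all 4 libraries. Leaving out vehicle replicate 1, dDAVP replicate 1, vehicle replicate 2 or dDAVP replicate 2 gave 32011, 46056, 14905 and 82002 dDAVP-only regions and 54275, 43316, 170990 and 29441 vehicle-only regions.

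Regions found in every library numbered 88231 (15.7%) and had a median width of 770 bp, whereas 297715 (53.1%) were found in 1 library, with a median width of 153 bp. The all-library regions took up 24.3% of the peaks of vehicle replicate 1, 33.0% of those of dDAVP replicate 1, and 46.1% and 46.2% of those of vehicle and dDAVP replicate 2. Of the all-library regions 16.9% were at gene ends, 36.7% were elsewhere inside genes and 46.4% were outside protein-coding genes.

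**Figure D3:**
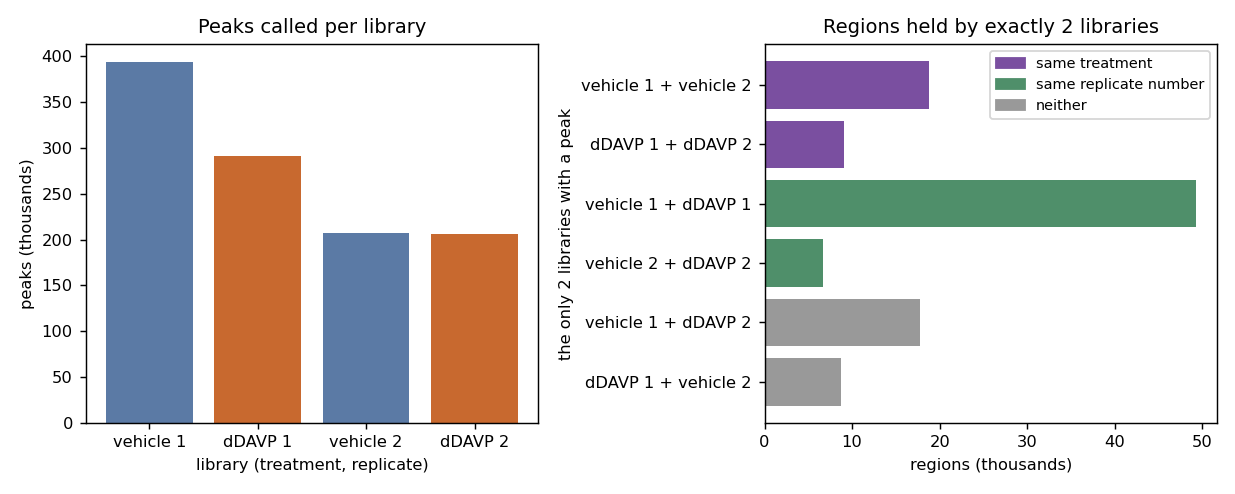
The left panel gives the number of peaks in each library (vertical axis, in units of 1000), blue for vehicle and orange for dDAVP. The right panel gives the number of merged regions (horizontal axis, in units of 1000) with a peak in exactly 2 libraries, for each pair of libraries; the pair of replicate 1 libraries holds 49261 regions, and the same-treatment pairs (18759 and 9045) lie close to the crossed pairs (17736 and 8774).

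The libraries did not sort by treatment. The Jaccard index, the shared length over the total length of 2 peak sets, was 0.373 for the replicate 2 libraries and 0.343 for the replicate 1 libraries, against 0.303 for the vehicle pair and 0.338 for the dDAVP pair, and the crossed pairs were at 0.298 and 0.341. The mean index of same-treatment pairs minus that of different-treatment pairs was -0.0177. The same difference was 0.0377 for the split by replicate number and -0.0200 for the crossed split. The mean number of peaks was 248612 ± 60587 after dDAVP and 300464 ± 132218 after vehicle (SD, n = 2, ratio 0.827, two-sided exact permutation p = 0.667). Covered length was 85.7 ± 17.1 Mb and 104 ± 41.6 Mb (SD, n = 2, exact permutation p = 0.667). The difference was smaller than the spread between the vehicle libraries, 2 against 2 cannot give an exact p under 0.333, and without vehicle replicate 1 the ratio of peak numbers turned to 1.20 and that of covered length to 1.16.

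A small excess of same-direction differences was present when the libraries were paired by replicate number. Among regions that differed by treatment in both replicates, the direction in replicate 1 went with the direction in replicate 2 with an odds ratio of 1.09 (95% block bootstrap interval 1.05 to 1.13, 1000 draws of 5 Mb blocks). This is the product of the vehicle-only and dDAVP-only counts over the product of the crossed counts. The value was 1.16 (0.977 to 1.40) at gene ends and 1.09 elsewhere. It depended on how peaks were matched and chosen, with 1.04 (1.005 to 1.071) when an overlap of 50% of both peaks was required and 1.05 (1.006 to 1.098) with only the peaks at least as wide as the median of their library, both applied here after seeing the data. The interval covers the spread over the genome in these 4 libraries and not the spread between cultures. The labels do not say that replicate numbers mark pairs. Vehicle replicate 1 may instead be paired with dDAVP replicate 2, and dDAVP replicate 1 with vehicle replicate 2. The vehicle-only and dDAVP-only counts (18759 and 9045) are then set against 49261 and 6642. The product of the latter is larger, so that ratio lies below 1, and the excess rests on the pairing.

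At the level of genes, 46 had a gene-end peak in both dDAVP libraries and neither vehicle library, and 189 had the reverse, against 49 and 142 in the crossed pairs (odds ratio 1.25 with libraries paired by replicate number, Fisher's exact p = 0.351). Of the 323 genes in the fixed lists none gained a gene-end peak with dDAVP by this rule with windows of 1 kb, and 3 lost one. These were the intercalated-cell anion exchanger gene Slc4a9, the collagen gene Col1a2 and the cardiac myosin gene Myh7, each with a peak in both vehicle libraries and neither dDAVP library. With all 4 libraries and windows of 1 kb, none of the 24 tests of a list in a direction passed Fisher's exact test with or without adjustment, and the lowest unadjusted p was 0.159, for the intercalated-cell list. Of these, the 8 tests on the bZIP, early, epithelial and housekeeping lists say nothing about dDAVP, since at most 1 gene of each was open in some libraries and not in others, which leaves 16. Those 16 could pass only with a large change, since their lists held 16 to 40 genes. Over all protein-coding genes 0.210% gained a peak and 0.864% lost one, and the 3 losses among 323 list genes are near that share. Which list genes changed depended on the window. With windows of 2.5 kb, Nedd4l and Oxgr1 gained a peak and only Col1a2 lost one, and with windows of 0.5 kb none gained and Sst, Slc4a9, Cdh5, Myh7 and Snap25 lost one. Single libraries mattered as well. Without vehicle replicate 1, 10 list genes gained a peak and 3 lost one, without dDAVP replicate 1 the numbers were 0 and 12, without vehicle replicate 2 they were 0 and 21, and without dDAVP replicate 2 they were 1 and 6. No list passed with adjustment under any of these settings (lowest adjusted Fisher's exact p = 0.126), although each had 1 or 2 of its 24 tests under an unadjusted 0.05. Over all genes the number of gains was 519 without vehicle replicate 1, 276 without dDAVP replicate 2, 132 without dDAVP replicate 1 and 87 without vehicle replicate 2. The number of losses was 276, 336, 741 and 937 in the same order.

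Of the dDAVP-only regions 3.73% were at gene ends, against 4.13% of the vehicle-only regions (a difference of -0.400 percentage points, two-sided Fisher's exact p = 0.117). The replicate 2-only and replicate 1-only regions differed by 0.437 points (Fisher's exact p = 0.0848), and the crossed pairs, dDAVP replicate 1 with vehicle replicate 2 minus vehicle replicate 1 with dDAVP replicate 2, by -0.0955 points (Fisher's exact p = 0.734). With each library reduced to its widest 205771 peaks, a setting chosen after seeing the data, the treatment difference was -0.709 points (Fisher's exact p = 0.00760). It was -0.130 points with a reciprocal overlap of 50% (Fisher's exact p = 0.598) and -0.349 points with windows of 2.5 kb (Fisher's exact p = 0.336). The other splits are not given for these settings. Regions are not replicates, so these tests describe the 4 libraries and not a population of cultures.

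The dDAVP-only region whose peaks ranked widest within their libraries was on chromosome 10 from 44412655 to 44413701, 23.5 kb from Prdm1, which encodes a transcriptional repressor, and outside protein-coding genes. The next were inside Wfdc8 (chromosome 2, 164598062 to 164599102), inside Pcbp3 (chromosome 10, 76903256 to 76904332) and inside Rasal1 (chromosome 5, 120668297 to 120669838). Others among the first 10 were inside Atrnl1, Pced1b and Phactr3, 11.9 kb from Smim41 and 84.5 kb from Zfp36l1. Of the vehicle-only regions the first was inside the nuclear receptor coactivator gene Ncoa2 (chromosome 1, 13191591 to 13192761). It was followed by regions 71.9 kb from Rbfox1 (chromosome 16, 5811461 to 5812918), 42.1 kb from Gm4737 (chromosome 16, 46197210 to 46198220) and inside Arhgef40 (chromosome 14, 51995599 to 51996589). The other 6 were inside Tmem116 and the growth factor gene Hbegf, and 12.5 kb from Zmat3, 33.1 kb from St6galnac3, 177 kb from Nrp1 and 59.9 kb from Iqub. None of these regions was tested singly, and the dDAVP-only and vehicle-only classes numbered 1.03 and 1.06 times the crossed classes that hold the same replicate 1 library. For the dDAVP-only class this turned to 0.982 with a reciprocal overlap of 50%, and it was 1.00 with the peaks at least as wide as the median, while the vehicle-only class stayed at 1.05 in both.

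The fourth item was the surroundings of Aqp2 itself, the gene that vasopressin induces in these cells. Aqp2 lies on chromosome 15 from 99579056 to 99584545, between Faim2 and the related aquaporin genes Aqp5 and Aqp6. From 100 kb before the gene to 100 kb after it there were 109 merged regions, of which 30 were present in all 4 libraries, 14.6 per 100 kb against 5.00 per 100 kb over chromosome 15 and 8.90 per 100 kb on the part of that chromosome beyond 72 Mb, which is richer in regions. Of 155 windows of the same length on that part, 23 held at least as many all-library regions. Counting regions of any library, the window was ordinary for that part, with 109 against a median of 108 per window, and 76 of the 155 windows held at least as many. A region of 1810 bp present in all 4 libraries covered the start coordinate of Aqp2 (99577682 to 99579491), and others of 497 and 672 bp lay at its end coordinate (99583746 to 99584242 and 99584583 to 99585254).

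Away from gene ends, 22 regions were present in all 4 libraries. The widest of them was 2344 bp long between Aqp6 and Racgap1 (99613644 to 99615987, 29.1 kb from Aqp2). Others were 1823 bp long inside Faim2 (99511816 to 99513638), 1545 bp long between Faim2 and Aqp2 (99563834 to 99565378, 13.7 kb from Aqp2) and 1509 bp long in the same interval (99549759 to 99551267, 27.8 kb). A region of 2530 bp lay at an end of Faim2 (99497139 to 99499668). In the window 1 region was found in both dDAVP libraries only, 361 bp long and 73.8 kb beyond Aqp2 (99658371 to 99658731), between Racgap1 and Asic1. There were 4 regions in both vehicle libraries only, inside Faim2 (99527551 to 99527906), at 99610136 to 99610258, at an end of Racgap1 (99619731 to 99620009) and inside Racgap1 (99641295 to 99641783). The window held 77 and 53 regions for the vehicle libraries and 64 and 57 for the dDAVP libraries, replicates 1 and 2 in turn, and 5 treatment-specific regions are too few for a test.

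**Figure D4:**
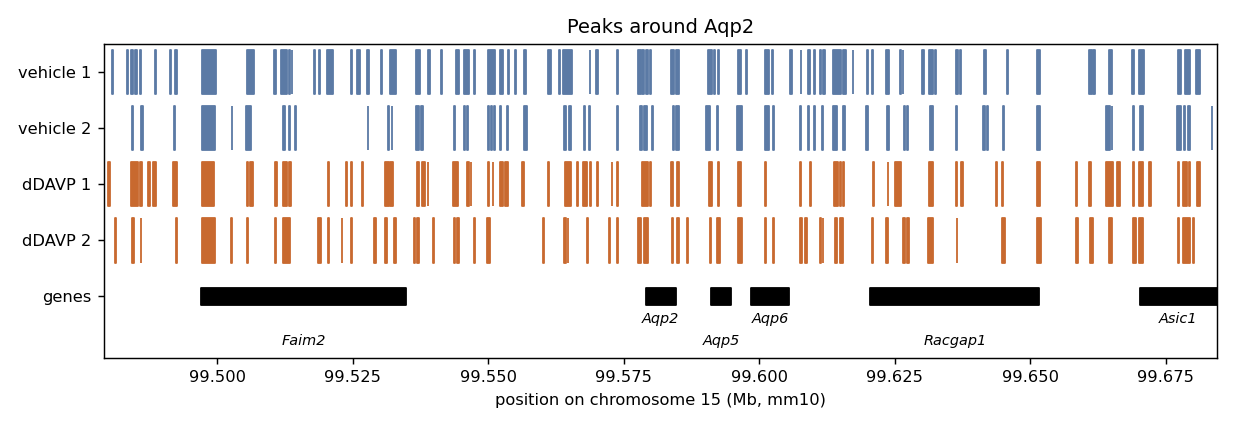
Peaks of the 4 libraries (rows, blue for vehicle and orange for dDAVP) from 100 kb before to 100 kb after Aqp2 on chromosome 15 (horizontal axis, Mb), with the protein-coding genes as black bars. The peaks over the start of Aqp2 at 99579056 and within Faim2 line up in all 4 rows.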

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

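The widest-peak, median-width, chromosome-stratified, whole-gene, receptor-free and length-matched settings, the background of distal chromosome 15 and the odds ratio of same-direction differences were chosen after seeing the data. Leaving out 1 library at a time moved the ratio of peak numbers, dDAVP over vehicle, between 0.631 and 1.20 and that of covered length between 0.645 and 1.16, with both above 1 only without vehicle replicate 1 (1.20 and 1.16). It moved the dDAVP-only regions between 14905 and 82002, the vehicle-only regions between 29441 and 170990, the genes gaining a gene-end peak between 87 and 519 and those losing one between 276 and 937, all above the values with 4 libraries because 1 library fewer has to lack or hold a peak. A reciprocal overlap of 50% gave 14538 dDAVP-only regions, and the median-width setting gave 4974 dDAVP-only and 9626 vehicle-only regions. The widest-peak setting gave 12381 vehicle-only regions, 85 genes gaining a peak and the difference in gene-end share of -0.709 points (Fisher's exact p = 0.00760), and the cause was not tested. This difference in share was smaller in size with the other settings, and regions are not replicates. A peak in any 1 library left 3 gene lists past the threshold in place of 5. Of the 2 lists with more regions within 50 kb, 0 passed against genes matched on gene-end peaks and 4 lists passed against genes matched on chromosome and length. The 55 other values of this kind stayed on their side of the threshold, within 1.5 times the count or within the spread between replicates. The labels do not say that replicate numbers mark a shared culture or day. With the replicate number as a block the ratio of peak numbers was 0.858 and that of covered length 0.854 (exact sign-flip p = 0.5, the smallest possible), and the counts of 9045 and 18759 regions are the same by construction. Top-score, upper-half and motif alternatives were not run, since no score or sequence was used here. Unknown depth limits every statement on absence.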

Other observations

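The gene families, chromosome, same-direction and peak-width tests in this part were chosen after seeing the data, except that the tests of ubiquitous genes, chromosome mix, region width, gene ends and width changes had their outcomes set out before they were run.

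Beyond the fixed lists, gene families grouped by symbol differed widely in how often a gene end was open in all 4 libraries. Olfactory receptor genes were open at 55 of 1110 (4.95%), vomeronasal receptor genes at 13 of 355, the Pramel genes at 2 of 46, the alpha-defensin genes at 0 of 28 and the Rhox homeobox genes at 0 of 33, and cytochrome P450 genes at 38 of 99. At the other end stood the mitochondrial ribosomal protein genes (47 of 49 Mrpl and 29 of 29 Mrps), the Vps genes of vesicle sorting (35 of 35) and the RNA polymerase subunit genes (28 of 28), and 330 of 397 Zfp zinc finger genes were open. Of 152 families with 15 or more genes, 38 were open more often and 37 less often than other genes on the same chromosomes, by exact conditional tests with Benjamini-Hochberg adjustment. Unlike the fixed epithelial list, the keratin genes (35 of 53 Krt), claudin genes (14 of 35 Cldn) and cadherin genes (8 of 23 Cdh) were among the families open less often than other genes on the same chromosomes. Their adjusted p by the exact conditional test was 0.0169, 0.0479 and 0.000634 in that order. The keratin share, 66.0%, was near the 65.0% of all protein-coding genes, so it was lower only beside genes of the same chromosomes. Genes of a family often lie in clusters, so its members are not independent.

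The Hox genes, which hold positional identity along the body axis, were open at 11 of 11 in the Hoxa cluster, 9 of 10 in Hoxb, 8 of 9 in Hoxc and 6 of 9 in Hoxd, and none of them lacked a gene-end peak in every library. The window with the most all-library regions relative to its chromosome was on chromosome 4 from 145400001 to 145600000, beside Zfp990, with 57 regions, 20.6 times the mean of that chromosome. Of the 15 windows ranked highest by this ratio, 8 lay in the zinc finger gene clusters of chromosome 4. The ratio is raised by the low mean of that chromosome, 2.77 regions per window. By count, a window on chromosome 8 (69400001 to 69600000) held more, 62.

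The density of peaks differed 16.1-fold between chromosomes 19 and X. Gene content does not account for it, since peaks per protein-coding gene still differed 7.90-fold, and neither does a single odd library, since the lowest rank correlation of density between libraries over 20 chromosomes was 0.982 (Spearman's rho; chromosomes are not replicates). Genes that every cell uses (352 members of the Mrpl, Mrps, Psm, Nduf, Eif, Polr, Rpl and Rps families) were open at 79 of 84 on the 5 chromosomes of lowest density and at 257 of 268 elsewhere, a difference of 1.85 points (95% interval -3.52 to 7.73), too wide an interval to decide whether DNA content or sensitivity differs by chromosome. Their widest peaks were narrower on those 5 chromosomes, with medians of 846 and 994 bp (ratio 0.852, 95% interval 0.787 to 0.968, permutation p = 0.00277). A lower signal per site there would give such a difference. The groups were set by chromosome and genes on a chromosome are not independent, so the interval and p describe these genes and libraries only. A lower copy number of X, 18, 7, 4 and part of 13 may be a source that remains untested. Of the 36 list genes without a gene-end peak in any library, 24 lie on these 5 chromosomes, which hold 26.0% of the list genes. The 5 chromosomes were not alike in the share of open genes among those that every cell uses. It was 62.5% of 8 genes on chromosome 18, 90.9% of 11 on X and 94.7% of 19 on chromosome 4. On chromosomes 7 (34 genes) and 13 (12 genes) it was 100%.

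Vehicle-only regions outnumbered dDAVP-only regions 2.07 times. In replicate 1, with 1.35 times as many vehicle as dDAVP peaks, the regions with a peak in vehicle and not dDAVP were 2.06 times the reverse. In replicate 2 that ratio was 1.01 (87606 and 86758), but its lists are about equally long and list length largely sets the ratio, so it does not decide whether dDAVP closed regions. The vehicle-only regions were 1.06 times the regions held by vehicle replicate 1 and dDAVP replicate 2 alone, so the length of the vehicle replicate 1 list may account for most of the imbalance, whether through depth or another property of that library, and some closing by dDAVP stays open. With every list cut to its widest 205771 peaks the imbalance fell to 1.09 times (12381 and 11325), against 1.01 times for the 2 crossed pairs (11360 and 11232), although such a cut would also remove a broad loss of peaks. With a reciprocal overlap of 50% it was 1.37 times, against 1.28 for the crossed pairs.

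The odds ratio of 1.09 for same-direction differences between treatments is a hypothesis of a small effect of dDAVP on many sites. The mix of chromosomes does not explain it (1.09 within chromosomes, 95% interval 1.05 to 1.12), nor does region width (1.08 within deciles, 1.04 to 1.12), but it was lower with a reciprocal overlap of 50% (1.04, 1.005 to 1.071) and in the median-width setting (1.05, 1.006 to 1.098), with the lower bounds barely above 1. Whether gene ends carry more of it could not be decided, with a ratio of odds ratios of 1.06 (0.901 to 1.29). A property of the libraries that happens to follow the treatment, such as fragment length or background, stays open with 1 value per set of 4 libraries, and so does an effect of dDAVP. The excess also rests on pairing the libraries by replicate number, since the other pairing puts the ratio below 1.

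The widths of the 88231 all-library regions gave 0 regions past an adjusted p of 0.05 in limma for dDAVP against vehicle, and 4655 at an unadjusted p under 0.05 against 4487 for the crossed split, a ratio of 1.04. The split by replicate number gave 7167 at an unadjusted p under 0.05 and, like the crossed split, 0 past the adjusted threshold. Width changes of 2-fold were not recovered in the simulation with a pooled spread, so these widths leave open whether dDAVP changed them modestly or not at all.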
